A study of Rattus norvegicus with 12 samples.

How the data were processed

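RNA was measured by poly(A)-selected, 150 bp paired-end sequencing on a NovaSeq in 12 libraries. The labels give H9C2, a line derived from embryonic rat heart, and call the cells cardiomyocytes. The libraries fall into 4 groups of 3 biological replicates, all collected after 48 h. Ctrl cells were kept in 5.5 mM glucose, HG cells in 100 mM glucose, HG-Res cells in 100 mM glucose with 5 µM resveratrol, and HG-Res-SIRT7-Inh cells in the same medium with 5 µM resveratrol and 5 µM of a compound labelled a SIRT7 inhibitor. The treatment protocol names that compound SirReal2, which is widely sold as an inhibitor of SIRT2. No osmotic control, no inhibitor-alone group and no vehicle is described in the labels.

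Per the submitters' processing notes, reads were handled with Trimmomatic and the genome build was rn6. The aligner, the counting tool, the annotation and the test behind the tables are not given in the sources used here. Each of the authors' 4 deposited tables compares 2 groups and holds a value per library, a log2 fold change, a p-value and a q-value. The 3 tables among high-glucose groups list 20263 genes each, and a library shared by 2 tables has the same values in both. The table of HG against Ctrl holds 354 genes, all of them carrying the authors' mark, so Ctrl was measured here in those genes alone. In all 4 tables the mark up or down was met exactly where the unadjusted p-value was under 0.05 and the fold change over 1.5.

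The value columns are headed TPM in the deposited tables, but they behave as CPM, reads of a gene scaled to a fixed total per library, with no scaling by gene length. Low values in each library are whole multiples of 1 step of about 0.03 CPM. Dividing by the step gave between 99.71% and 100% of values within the rounding of 0.005 of a whole read, against about 40% at a median wrong step. That rounding is about 0.16 of a read, and in a stricter test, within 0.1 of a read, between 56.1% and 70.9% of the low values of 11 libraries passed, and 100% in HG replicate 2. The rounding alone exceeds 0.1 of a read, so exact whole reads can also fail the stricter test, which therefore cannot decide. The recovered reads were treated as approximate and not as counts. The recovered depth was 30.29 to 33.17 M reads per library. The recovered reads served the depth, the comparison of replicates, thinning and alternative settings, not the main test. The values allow a gene to be compared between libraries but not with another gene.

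All 20263 identifiers begin with ENSG, Ensembl's prefix for human genes, whereas the labels give rat and build rn6, for which Ensembl's prefix is ENSRNOG. None of the identifiers, 0 of 20263, matched the rat gene table (assembly GRCr8), and the files do not pair identifiers with names. Identifiers with a human prefix could hardly match a rat table, so the lack of a match does not decide the conflict. Whether the values come from rat or human genes is left open. No gene is named, no coordinate is given, and at most 2 identifiers that rose and 2 that fell are printed per comparison. The gene lists drawn up for this tissue and treatment, and the sirtuin genes, were therefore not analysed here.

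Genes with at least 0.5 CPM in at least 3 of the 9 high-glucose libraries were tested, 12854 in all. Values were used as deposited, with no further scaling, as log2(value + 1). They were fitted with limma 3.58.1 in R 4.3.3, using group means, 1 fit over HG, HG-Res and HG-Res-SIRT7-Inh, empirical Bayes with an intensity trend, and Benjamini-Hochberg adjustment at 0.05. Fold changes are on this log2(value + 1) scale and understate the change of low genes. P-values measure the spread between the samples labelled as biological replicates. The design fixed in advance named a count model for whole counts and this limma test otherwise. The filter level and the trend were set once the unit was known and before any fit. Printed identifiers had the largest changes among genes past the threshold with a mean of at least 1 CPM in the higher group and replicate values that did not overlap; the planned 10 per direction and the need for a symbol were dropped. For HG against Ctrl the same rule was applied to the authors' log2 fold change and q-value.

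The fit was tested on simulated data with 200 changed genes per comparison. Simulated libraries varied independently, with the same spread in every group at a given expression level. The real groups differed in spread and had genes that deviated together, so the shares and false calls below may not hold for the data. For HG-Res against HG (12827 simulated genes tested) it recovered 59.7% of 1.5-fold, 97% of 2-fold and 100% of 4-fold changes, with 13 false calls. For HG-Res-SIRT7-Inh against HG-Res (12826 genes) the shares were 53.7%, 95.5% and 100%, with 4 false calls, and for HG-Res-SIRT7-Inh against HG (12811 genes) 56.7%, 98.5% and 100%, with 6 false calls. To look for duplicate libraries, the approximate reads of replicate pairs were compared, where separate cultures are expected to differ by more than counting noise. The chi-square per degree of freedom lay between 5.26 and 172.8, so no pair was counted as 1 library.

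Comparisons that share libraries were set beside 2000 simulated draws in which the second treatment had no effect. Each draw took the errors of group means from the residuals of the fit, so that genes deviating together in the data did so in the simulation. Confidence intervals of shares of genes are exact 95% binomial intervals and treat genes as independent, which they are not. Alternatives covered scaling by median of ratios, filters, the pseudocount, the groups in the fit, the replicate number as a block, each library left out, limma voom on recovered reads and the authors' q-values. No per-sample column was left unused. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.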

Results

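Gene expression was measured in 12 libraries labelled H9C2, 3 for each of 4 conditions held for 48 h. The conditions formed a series: 5.5 mM glucose (Ctrl), 100 mM glucose (HG), 100 mM glucose with resveratrol (HG-Res), and the last with the addition of a compound labelled a SIRT7 inhibitor (HG-Res-SIRT7-Inh). Resveratrol is a plant polyphenol often used as an activator of sirtuins, a family of NAD-dependent deacylases. The depth recovered from the values was 31.69, 31.76 and 31.73 M reads in Ctrl and 31.81, 33.17 and 31.11 M in HG. It was 31.44, 31.63 and 31.91 M in HG-Res and 31.94, 31.15 and 30.29 M in HG-Res-SIRT7-Inh. The 10 most abundant genes took 6.62% to 7.87% of the reads of the 9 high-glucose libraries. Genes are given by the identifiers in the files, whose human-style prefix conflicts with the rat label, and are not named. Levels are given in CPM, the reads of a gene scaled to a common total per library.

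Replicates differed in how closely they agreed. The median SD between replicates, over 12854 genes on the log2 scale, was 0.132 in HG, 0.071 in HG-Res and 0.242 in HG-Res-SIRT7-Inh. The first principal component took 56.1% of the variance and ran between HG replicate 2 (29.7) and HG-Res-SIRT7-Inh replicate 3 (-50.7), with the other 7 libraries between -17.1 and 14.4. The second took 20.3% and placed HG replicates 1 and 3 (15.2 and 18.7) apart from HG-Res (-2.4 to -0.4) and from HG-Res-SIRT7-Inh replicates 1 and 2 (-24.4 and -16.8). HG replicate 2 and HG-Res-SIRT7-Inh replicate 3 lay at 4.4 and 6.7 on it.

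**Figure D1:**
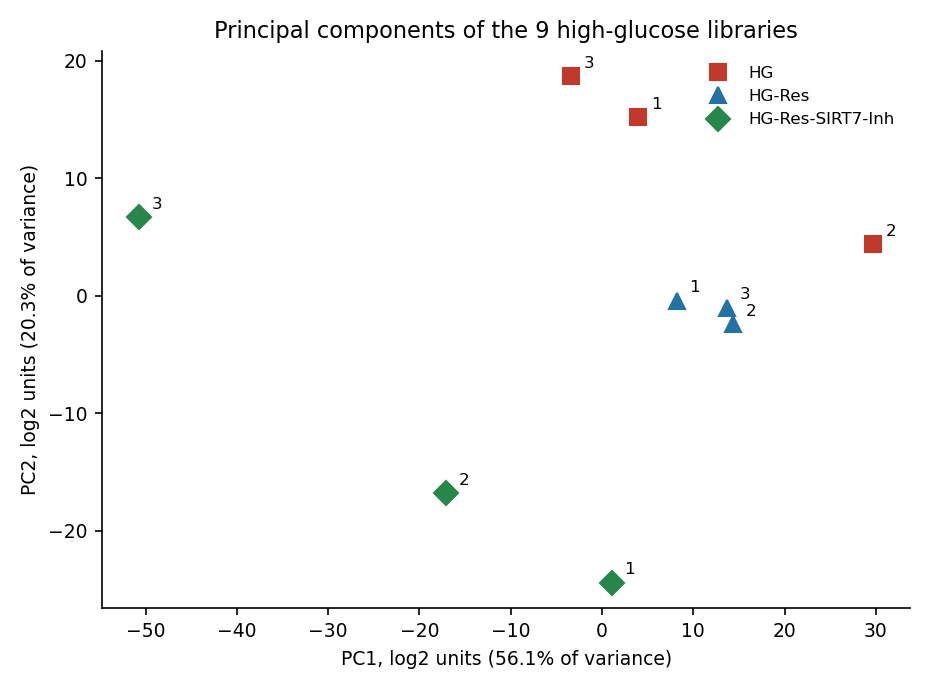
First 2 principal components of log2(value + 1) over 12854 genes in the 9 high-glucose libraries, in log2 units, with 1 point per library numbered by replicate. HG replicate 2 at 29.7 and HG-Res-SIRT7-Inh replicate 3 at -50.7 mark the ends of the first component.

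The first comparison asked which genes responded to high glucose. The authors' deposited table marked 354 genes, 95 higher and 259 lower in HG than in Ctrl. Of these, 178 had a q-value under 0.05 in the authors' deposited table, 45 higher and 133 lower. ENSG00000116701 was at 1.44 ± 0.299 CPM in Ctrl and 3.23 ± 0.338 in HG (SD, n = 3), and ENSG00000183114 went from 1.04 ± 0.19 to 2.2 ± 0.471. Among the lower genes, ENSG00000139269 was at 11.1 ± 0.142 CPM in Ctrl and 2 ± 0.682 in HG, and ENSG00000128165 at 16.6 ± 0.687 and 5.39 ± 0.804. The authors' deposited table gave these 4 genes log2 fold changes of 1.22, 1.14, -2.39 and -1.55, with q-values of 3.58e-05, 0.00366, 2.56e-21 and 4.39e-24. The replicate values of HG and Ctrl did not overlap in 174 of the 178 genes. Because the table holds marked genes alone, no test across all genes could be run for glucose, and 176 of its 354 genes had a q-value of 0.05 or more.

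The second comparison asked what resveratrol changed in high glucose. In limma with Benjamini-Hochberg adjustment, 91 genes passed an adjusted p of 0.05 between HG-Res and HG, of which 42 rose and 49 fell. ENSG00000157601 rose from 23.9 ± 0.553 to 69.5 ± 1.98 CPM (SD, n = 3), a log2 change of 1.5 ± 0.1 (SE, limma adjusted p = 0.000276). ENSG00000138135 rose from 1.35 ± 0.38 to 5.53 ± 1.33 CPM, by 1.47 ± 0.17 (limma adjusted p = 0.00454). ENSG00000114812 went from 15.3 ± 0.643 to 2.78 ± 0.15 CPM, a log2 change of -2.10 ± 0.13 (limma adjusted p = 0.000237). ENSG00000169429 went from 16 ± 0.684 to 4.19 ± 0.75 CPM, a change of -1.72 ± 0.17 (limma adjusted p = 0.00257). Among the 91 genes, 22 changed at least 2-fold, 10 up and 12 down. The median change of all genes was -0.001, and the replicate values of the groups did not overlap in 29.9% of genes, where chance gives 10% on average. Genes deviated together, so a single chance split could lie well above that average, and its spread was not computed.

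The number of genes depended on the model and on which libraries set the spread: it was 45 with the replicate number as a block, 596 with HG and HG-Res alone in the fit, 801 without HG-Res-SIRT7-Inh replicate 3, and 2722 without that library and HG replicate 2. It was 19 to 26 without HG replicate 1 or 3 or any 1 HG-Res replicate, 54 without HG replicate 2 and 48 without HG-Res-SIRT7-Inh replicate 2. Genes that rose outnumbered those that fell in the 2-group fit (318 and 278), without HG-Res-SIRT7-Inh replicate 3 (421 and 380) or replicate 2 (25 and 23) and without HG replicate 2 and HG-Res-SIRT7-Inh replicate 3 (1434 and 1288). They did so too with all 9 libraries under median-of-ratios scaling (44 and 43) or with the replicate number as a block (23 and 22), and by the authors' q-values (602 and 489), so the balance of rises and falls depends on the setting. The authors' q-values, from a test not given in the sources used here, called 1091 genes, and all 91 genes were among these, the 596, the 801 and the 2722.

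Whether resveratrol moved the glucose genes back toward Ctrl was asked of the 251 listed genes that were expressed in the high-glucose libraries. The change with resveratrol was opposite to the change with glucose in 121 of them, 48.2% (95% interval 41.9 to 54.6). Draws in which resveratrol had no effect gave a median of 53.6% (31.8 to 74.8), above an even split because both comparisons use the HG libraries. Among the 42 members that changed at least 2-fold with glucose the share was 61.9%, above an even split, against 52.6% (33.3 to 73) in draws, of which 524 reached it. At an adjusted p under 0.05 in limma, 2 listed genes moved opposite to the glucose change and 8 moved further in its direction. Of the 72 listed genes raised by glucose 47 were higher still in HG-Res, 65.3%, against 43.8% (25.9 to 63.9) in draws with no effect, of which 29 of 2000 reached it. Of the 179 lowered by glucose 96 were higher in HG-Res, 53.6%, against 52.1% (26.9 to 76.6).

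The same was asked of the genes with a q-value under 0.05. Of the 45 tested genes raised by glucose, 37 were higher still in HG-Res, with 7 that rose and 2 that fell. That share, 82.2%, compares with 46.2% (27.6 to 62.8) in draws with no effect, and 0 of 2000 draws reached it. The counts were 13 and 3 without HG-Res-SIRT7-Inh replicate 3, 12 and 2 with the 2 groups alone, 18 and 3 without that library and HG replicate 2, 4 and 1 without HG-Res replicate 2, and 5 to 8 and 1 to 2 without any other single library. Of the 126 genes lowered by glucose, 65 were higher and 61 lower in HG-Res, with 0 that rose and 1 that fell in limma (5 rose at an unadjusted p under 0.05, 0 with voom and 3 by the authors' q-values). Here 1 rose and 9 fell without HG-Res-SIRT7-Inh replicate 3, 0 and 8 did with the 2 groups alone and 7 and 16 without that library and HG replicate 2, while 0 and 0 passed without any 1 HG or HG-Res replicate or HG-Res-SIRT7-Inh replicate 2. ENSG00000139269 and ENSG00000128165, lowered by glucose, were at 2.17 ± 0.0635 and 5.8 ± 0.645 CPM in HG-Res, and neither passed the limma threshold against HG (adjusted p = 0.924 and 0.919).

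The libraries were also placed on the line from the Ctrl mean (0) to the HG mean (1) over the 171 listed genes with a q-value under 0.05. HG-Res lay at 1.14 ± 0.01 (SD, n = 3), with all 3 libraries beyond the 3 HG libraries, which spread from 0.923 to 1.048. Draws with no resveratrol effect gave a position of 0.98 (0.80 to 1.10), and 13 of 2000 reached the observed one. HG-Res-SIRT7-Inh lay at 0.92 ± 0.15, with libraries at 0.788, 0.879 and 1.089. The HG libraries both chose these genes and set the line, and the q-value limit, the split by direction and this measure were chosen after seeing the data.

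**Figure D2:**
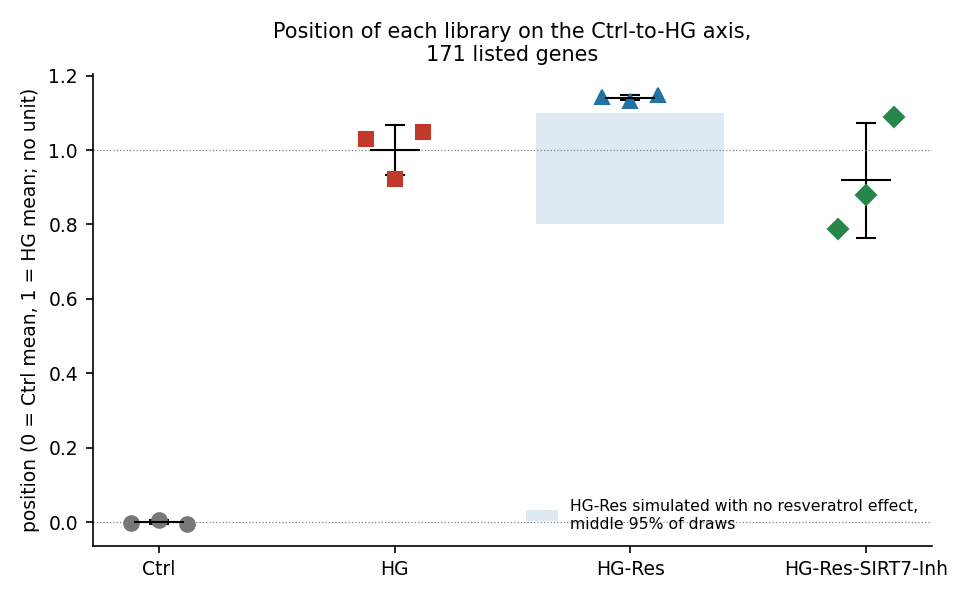
Position of each library between the Ctrl mean (0) and the HG mean (1) over 171 listed genes, with group mean and SD (n = 3) and a band holding the middle 95% of draws with no resveratrol effect. The HG-Res libraries, at 1.133 to 1.147, lie above the band, which ends at 1.10.

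The third comparison asked what the inhibitor changed in cells given resveratrol. Between HG-Res-SIRT7-Inh and HG-Res, 780 genes passed limma's adjusted p of 0.05, and 242 rose while 538 fell. Of the 132 genes that changed at least 2-fold, 119 fell. ENSG00000135114 went from 186 ± 5.48 CPM in HG-Res to 26.5 ± 5.52 (SD, n = 3), a log2 change of -2.78 ± 0.14 (SE, limma adjusted p = 6.73e-06). It had been at 45.5 ± 1.59 in Ctrl and 69.5 ± 4.34 in HG. ENSG00000271503 went from 32.4 ± 1.99 to 4.37 ± 0.387 CPM, a change of -2.64 ± 0.11 (limma adjusted p = 3.21e-06). ENSG00000054356 rose from 1.18 ± 0.201 to 4.54 ± 1.34 CPM, by 1.32 ± 0.17 (limma adjusted p = 0.00189). ENSG00000204334 went from 0.38 ± 0.35 to 2.31 ± 0.682 CPM, a change of 1.28 ± 0.24 (limma adjusted p = 0.0142). Its call was lost without HG-Res replicate 1 or 2 and under voom (limma adjusted p = 0.0536, 0.0543 and 0.0612, the last the highest of 20 alternatives, of which 0.00266 was the lowest).

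The count was 414 with the 2 groups alone in the fit, 457 without HG replicate 1, 276, 280 and 278 without each HG-Res replicate and 348 without HG-Res-SIRT7-Inh replicate 2. It was 1778, of which 836 rose and 942 fell, without HG-Res-SIRT7-Inh replicate 1, 1175 without replicate 3, and 2412, of which 1236 rose, without HG replicate 2 and HG-Res-SIRT7-Inh replicate 3.

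Whether the inhibitor undid the resveratrol changes was asked of the 91 resveratrol genes. It differed by direction. Of the 42 genes that rose with resveratrol, 31 fell when the inhibitor was added and 0 rose in limma, with 0 that rose also at an unadjusted p under 0.05, with voom and by the authors' q-values. In 2000 draws with no inhibitor effect, which keep the shared HG-Res libraries, 0 reached the share that fell, 73.8%. Past the threshold or not, 38 of the 42 risen genes were lower with the inhibitor, 90.5%. The draws gave a median of 61% for this (30 to 89), and 36 draws reached the observed share. For the 31 and 0, independent lists, which leave out the sharing, would have 1.8 and 0.8 genes in common. Of the 49 that fell with resveratrol, 1 rose with the inhibitor and 20 fell further (0.9 and 2.1 for independent lists). The share that fell further, 40.8%, was reached by 0 draws. Past the threshold or not, 85.7% were lower with the inhibitor, against 40% (15.3 to 65.9) in the draws, and 0 draws reached it. All 49 were below their HG mean with the inhibitor present, and 18 of the 42 risen genes were still above theirs. Of the 31 risen genes that fell with the inhibitor, 24 ended below their HG mean, 15 of them past limma's threshold against HG. The draws ask whether the inhibitor had any effect, and cannot separate undoing the resveratrol rise from lowering genes in general. ENSG00000157601, raised by resveratrol, ended at 12.8 ± 1.35 CPM, below HG (limma adjusted p = 0.000919), beside a Ctrl level of 15.3 ± 0.326 that was not tested against it. ENSG00000114812, lowered by resveratrol, went further down to 0.687 ± 0.278 CPM, and ENSG00000169429 to 1.79 ± 0.724.

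Over both directions 45 of 91 genes moved opposite to resveratrol, 49.5% (95% interval 38.8 to 60.1), while draws with no inhibitor effect gave 60% (36.4 to 83.8) because the HG-Res libraries are shared. The draws gave HG-Res the pooled spread, wider than its own, so this simulated share may be too high. The covariance of the 2 sets of fold changes over all genes was -0.0154, against -0.0095 (-0.0914 to 0.0211) in those draws, of which 760 were as low. The correlation was -0.22, against -0.31 (-0.81 to 0.48), and 1161 draws were as low. With the HG-Res libraries split so that none was shared, the covariance was -0.0137 to -0.0025 and the correlation -0.19 to -0.03. Genes called anew in each of the 6 splits, 4 to 32 in number, moved opposite in 43.8% to 75%. With HG-Res replicate 2 alone against HG, 5 of 25 risen genes then fell and 1 rose, while the other 5 splits had 3 to 10 risen genes, of which all then fell except 1 of 9 in 1 split. A lone library was assumed to vary like the other groups. The authors' deposited tables gave 66.1% of 1091 genes, and the fits with 2 groups alone 62.2% of 596.

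**Figure D3:**
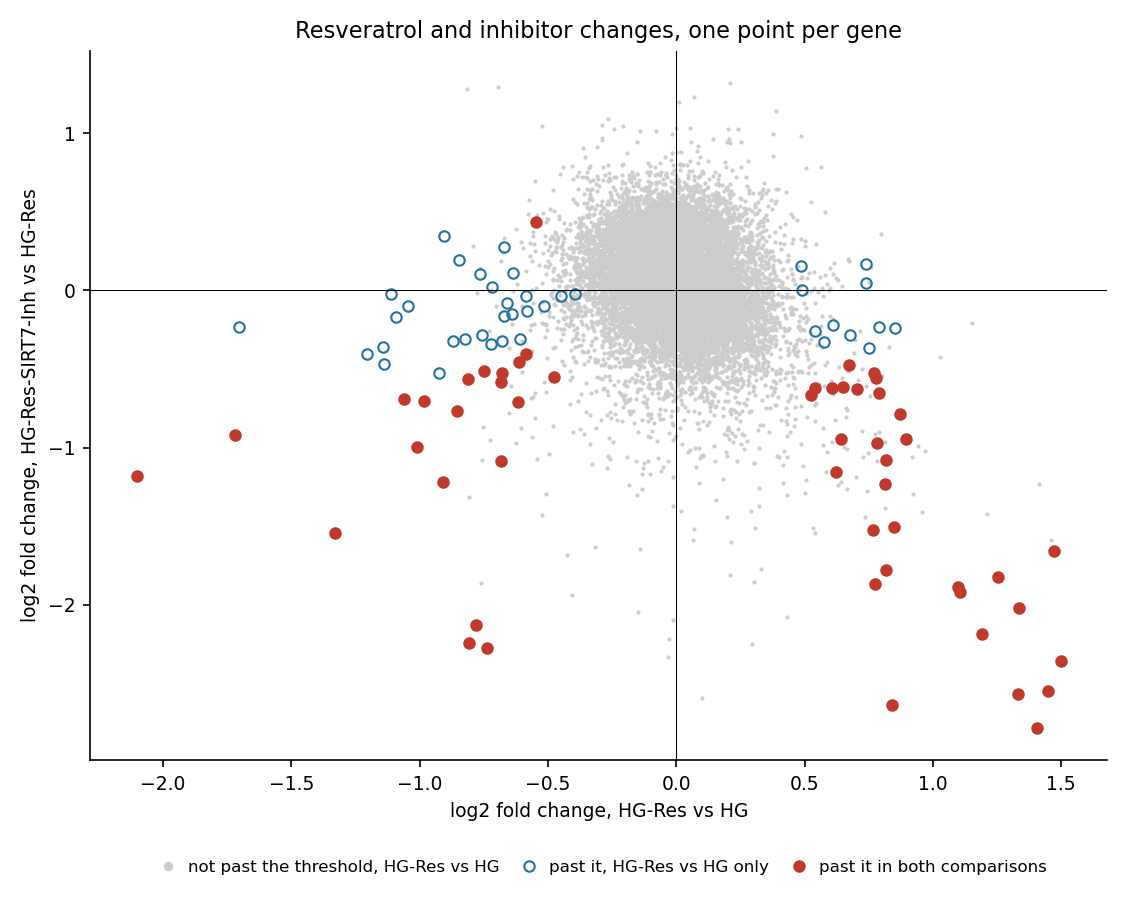
Log2 fold change with resveratrol (horizontal) and with the inhibitor added to it (vertical), 1 point per gene, with the 91 genes past the threshold for resveratrol marked and filled where they also passed it for the inhibitor. Of the filled genes, 31 lie at lower right, 20 at lower left, 1 at upper left and 0 at upper right.

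The last comparison set resveratrol and inhibitor together against high glucose alone. In limma, 1385 genes passed an adjusted p of 0.05, of which 549 rose and 836 fell. Of the 156 that changed at least 2-fold, 131 fell. ENSG00000114812 went from 15.3 ± 0.643 CPM in HG to 0.687 ± 0.278 (SD, n = 3), a log2 change of -3.28 ± 0.13 (SE, limma adjusted p = 1e-06). ENSG00000164761 went from 150 ± 8.39 in HG through 85.3 ± 4.12 in HG-Res to 17.4 ± 2.86 CPM, -3.05 ± 0.12 against HG (limma adjusted p = 1.22e-06). ENSG00000107796 rose from 8.47 ± 0.89 to 26.5 ± 4.12 CPM, by 1.53 ± 0.13 (limma adjusted p = 0.00014). ENSG00000054356 rose from 0.883 ± 0.101 to 4.54 ± 1.34 CPM, also by 1.53 (SE 0.17, limma adjusted p = 0.000536).

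The count was 420 with the 2 groups alone, 549, 715 and 858 without each HG replicate, 851, 844 and 834 without each HG-Res replicate, and 2171, 639 and 2717 without each HG-Res-SIRT7-Inh replicate. The excess of falls was lost without HG-Res-SIRT7-Inh replicate 3, where 1370 rose and 1347 fell, and small without replicate 1, at 1044 and 1127. Without HG replicate 2 and HG-Res-SIRT7-Inh replicate 3 the count was 3991, of which 2138 rose and 1853 fell.

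**Figure D4:**
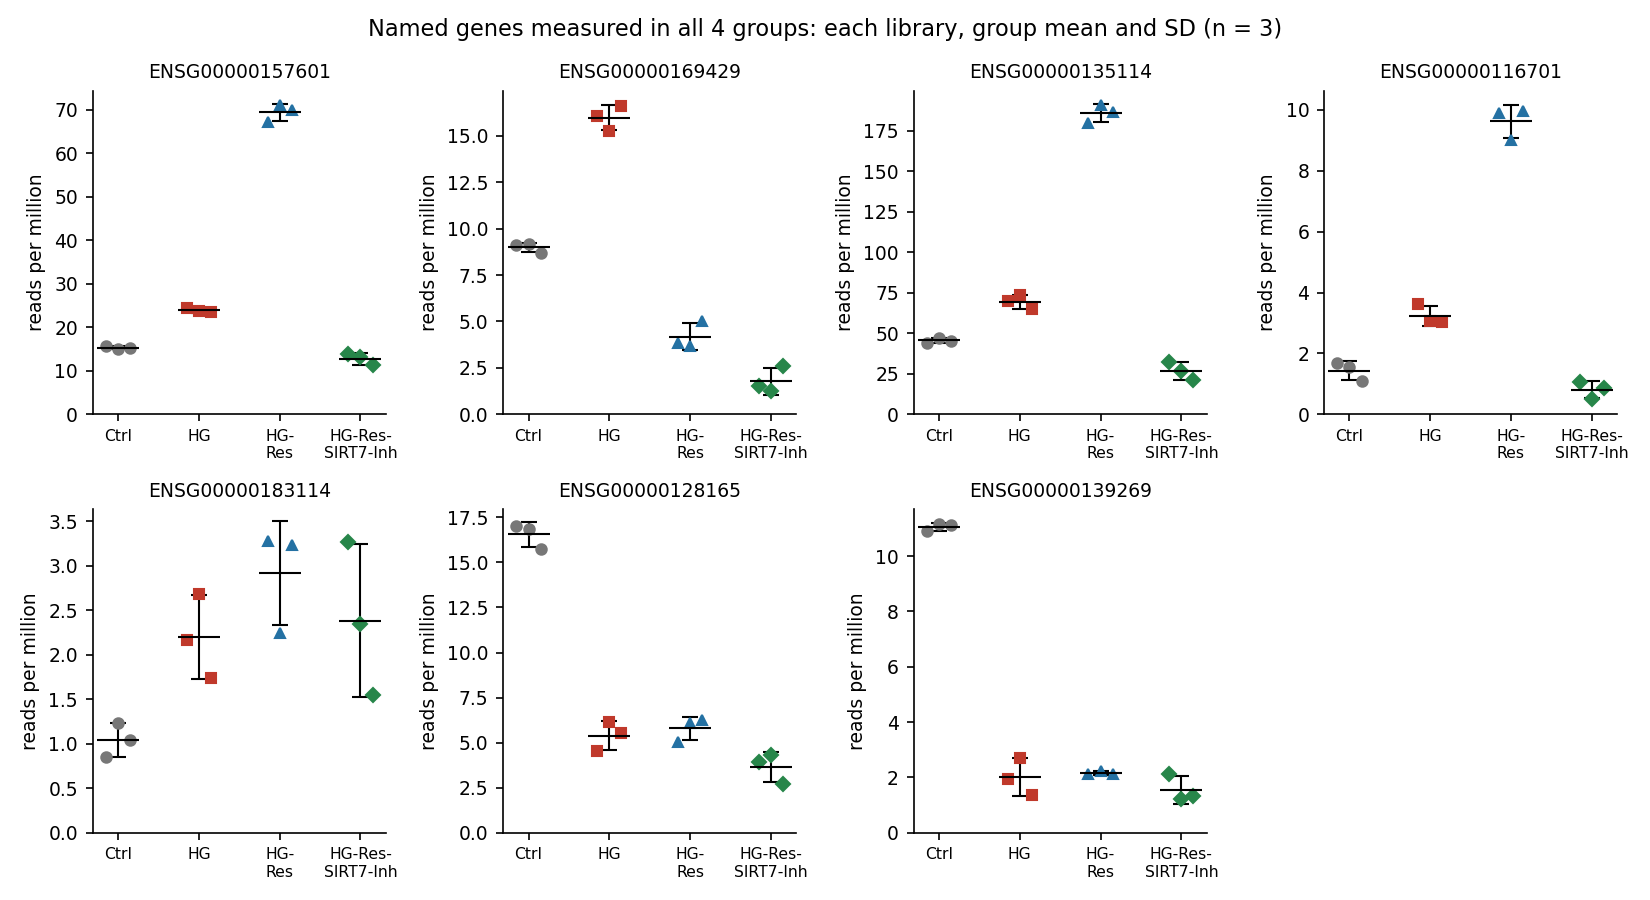
CPM of the 7 printed genes with values in all 4 groups, 1 point per library, with group mean and SD (n = 3). ENSG00000157601, ENSG00000135114 and ENSG00000116701 have their highest means in HG-Res (69.5, 186 and 9.62) and their lowest in HG-Res-SIRT7-Inh (12.8, 26.5 and 0.81).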

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

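The groups, comparisons, pseudocount, shared fit, naming rule and most alternatives were set before the data were examined. The filters at 0.5 and 1 CPM, voom, a single prior variance, the joint removal of HG replicate 2 and HG-Res-SIRT7-Inh replicate 3, and the q-value limit of 0.05 on the glucose list were chosen after seeing the data. So were the 2-group and voom settings, and the draws by direction, for the resveratrol genes, and the draws for 2-fold glucose genes. Each count among the high-glucose groups was recomputed under 21 alternatives, that of the glucose list under 4.

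The number of genes stayed within 1.5 times its value in all 3 comparisons under median-of-ratios scaling, no filter, at least 10 recovered reads or 1 CPM, a pseudocount of 0.1, voom and a single prior variance. Between HG-Res and HG (91 genes) it was 22 at 2-fold or more, 1091 by the authors' q-values, 596 with 2 groups, and 2722 without both libraries. Between HG-Res-SIRT7-Inh and HG-Res (780) it was 132 at 2-fold, 414 with 2 groups and 2412 without both, and between HG-Res-SIRT7-Inh and HG (1385) 156, 420 and 3991. The 2 libraries removed jointly were chosen for standing apart, so these higher counts are not independent estimates. The 2-group fit of HG-Res and HG leaves out HG-Res-SIRT7-Inh, with its wider spread. The 2-group fits with HG-Res-SIRT7-Inh leave out HG or HG-Res, with their narrower spread, and gave fewer genes than the shared fit.

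Leaving out 1 library gave 19 (HG-Res replicate 2) to 801 (HG-Res-SIRT7-Inh replicate 3) genes for the first, 276 (HG-Res replicate 1) to 1778 (HG-Res-SIRT7-Inh replicate 1) for the second, and 549 (HG replicate 1) to 2717 (HG-Res-SIRT7-Inh replicate 3) for the last. Every library moved at least 1 of these counts by over 1.5 times, with values in the report. The share of glucose genes moved back by resveratrol ranged from 41% to 48.6%, and that of resveratrol genes moved back by the inhibitor from 45% to 54.2%.

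The glucose list fell from 354 genes to 138 at a q-value under 0.01, 124 at 2-fold or more, 178 at a q-value under 0.05, and 174 when replicates also did not overlap. Its share moved back was 61.9% among the 42 tested members that changed 2-fold. The share moved back by the inhibitor was 66.1% in the authors' tables and 62.2% with 2 groups; the cause was not tested. Of the calls of printed genes, 190 of 192 held under alternatives set in advance and 47 of 48 under later ones, none reversed, and the 3 lost all concern ENSG00000204334. Printed genes were picked for the largest changes in these same libraries, so such survival was likely from the start. It does not speak for the other calls.

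Replicate numbers did not pair the samples: same-numbered deviations correlated at -0.55 to 0.64. With the number as a block the counts were 45, 649 and 1112. DESeq2 and TMM scaling were not run, nor were tests of gene lists, for want of gene names. At about 30 M reads, 1 read is worth about 0.03 CPM, and the 0.5 filter leaves genes below it untested.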

Other observations

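The 3 patterns below were noticed in the data. The tests of the 2-fold falls, the position of HG replicate 2 between Ctrl and HG, and the count of other splits were chosen after related results had been seen.

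The genes raised by high glucose were also among those that fell with the inhibitor. Of the 45 tested genes raised by glucose at a q-value under 0.05, 40 were lower in HG-Res-SIRT7-Inh than in HG-Res, with a median log2 change of -0.92, and 30 fell and 1 rose at limma's adjusted p under 0.05 (21 to 32 and 0 to 1 with 1 library left out). Of the 126 lowered by glucose, 69 were lower and 57 higher, with a median of -0.03. The glucose list and this comparison share no library. Against HG, whose libraries the list shares, 36 of the 45 were lower with the inhibitor and 25 fell. ENSG00000116701 went from 1.44 ± 0.299 CPM in Ctrl to 3.23 ± 0.338 in HG, 9.62 ± 0.533 in HG-Res and 0.81 ± 0.278 in HG-Res-SIRT7-Inh (SD, n = 3).

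Technical explanations for the fall of glucose-raised genes were tested on all 45. Under median-of-ratios scaling 91.1% were lower, and 91.1% without HG-Res-SIRT7-Inh replicate 3, where scaling or that library as the cause called for under 65%. The scaling factors spanned 0.984 to 1.031, too narrow a range to move this share much, so that test does not decide on scaling. Chance deviation of whole libraries gave 51.1% (35.6 to 64.4), and 0 of 2000 draws reached the observed 88.9%. Those draws used a pooled spread, narrower than that of HG-Res-SIRT7-Inh itself. By the labels, HG-Res-SIRT7-Inh and HG-Res differ by the inhibitor alone, so an effect of adding it to resveratrol is what this comparison asks. No vehicle is described. Whether the inhibitor acted through any sirtuin, other targets or cell health was not tested. Nor was its effect without resveratrol, since no group was given the inhibitor alone.

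The second pattern is that 119 of the 132 genes that changed at least 2-fold between HG-Res-SIRT7-Inh and HG-Res fell, 90.2%. The share was 92.8% under median-of-ratios scaling (813 genes past the threshold rather than 780) and 93.6% without HG-Res-SIRT7-Inh replicate 3. With voom on recovered reads it was 80.4%, 213 of 265 genes. The shares without that library and with voom argue against that library or the pseudocount as the whole cause. Voom gave more 2-fold changes in both directions and a lower share of falls, so the size of the imbalance depends on the scale. The scaling factors spanned 0.984 to 1.031, too narrow a range to move 2-fold changes, so that test does not decide on scaling. Without HG-Res-SIRT7-Inh replicate 1 the share was 71.1%, 133 of 187 genes, so its size depends on that library. The falls were no fewer than the 119 with all libraries, so the lower share came from more rises. With HG replicate 2 and HG-Res-SIRT7-Inh replicate 3 removed, 93.7% of 2-fold changes were falls, but 51.2% of all genes past the threshold rose, against 31% with all libraries. By the labels these groups differ by the inhibitor alone, with no vehicle described, so the comparison asks about its addition to resveratrol. Through which target it acted was not tested.

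The third pattern is the distance between HG replicate 2 and HG-Res-SIRT7-Inh replicate 3 on the first principal component. After all libraries were thinned to 30.29 M reads 100% of it was left, and 99.6% without the 100 most abundant genes and with median-of-ratios scaling. Neither test decides: depths spanned 30.29 to 33.17 M and scaling factors 0.984 to 1.031, and few genes were removed, so the distance had little room to fall and depth, scaling and abundant genes stay open. On lines set by the other libraries, HG replicate 2 lay at most 0.2 of the way from HG to another high-glucose group, and at 0.85 between Ctrl (0) and HG (1) on genes chosen with it, while HG-Res-SIRT7-Inh replicate 3 lay at 0.78 or more of the way to its own group, so a wrong label among these groups is unlikely for either. No biological explanation was tested, and differences between cultures or library preparation stay open.

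Each comparison of 3 against 3 libraries has 10 splits, too few for a share under 0.05. The real split was the 1 split with as many genes in each comparison: 91, 780 and 1385 genes, with 0 in limma as the highest other count in all 3. At an unadjusted p under 0.05 the real splits gave 1369, 3167 and 3586 genes and the highest others 850, 1032 and 3589. The split with 3589 exchanged HG replicate 2 and HG-Res-SIRT7-Inh replicate 3. Its sides lay apart on the second principal component (6.7 to 18.7 against -24.4 to 4.4), not on the first. A split with 3181 put HG replicates 1 and 2 with HG-Res-SIRT7-Inh replicate 1. Its sides lay apart on the first component (1.1 to 29.7 against -50.7 to -3.4). Which structure of the samples beside the groups these splits follow was not tested.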
